A study of Caenorhabditis elegans with 4 samples.

How the data were processed

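Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole larvae of stage L3 of Caenorhabditis elegans of the laboratory wild-type strain N2, with an antibody against EPC-1. The series holds 4 samples, 2 EPC-1 immunoprecipitations numbered as replicates 1 and 2 and 2 input DNA samples, and the labels name a separate input for each immunoprecipitation. Processed files were used for the 2 immunoprecipitations. The input DNA has no file here and was not analysed. Per the labels' protocols, ground frozen animals were fixed with the amine-reactive crosslinker EGS for 20 min and then with EGS plus formaldehyde for 10 min. A second protocol text in the same labels describes formaldehyde alone, and the sample titles carry EGS. Chromatin was sonicated, fragments of 250 to 500 bp were cut from a gel and libraries were amplified for 18 cycles.

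The reads were aligned with BWA, per the submitters' processing notes, and its version is not given in the sources used here. Each deposited file is a list of binding sites called by the authors on 1 immunoprecipitation, in coordinates of WormBase release WS190, per the file headers. The peaks are named after the caller MACS, and the file names carry the same name, whereas the source column of every row names another program, MA2C. The caller's settings, its use of the input and the number of reads are not given in the sources used here. The deposited score of each peak is the authors' own value for that peak, and its scale is not stated. Its lower limit and its tied upper value resemble the scaled logarithm of a p-value that MACS writes, which no source used here states. Such a score depends on read depth and background as well as on enrichment, so a low score is not read here as low occupancy. The scores run from 50.01 in replicate 1 and 50.03 in replicate 2, so the authors' lists end at a score of about 50. At the other end the score saturates, since 211 peaks of replicate 1 and 198 of replicate 2 carry exactly 3100. A further 13 peaks of replicate 1 and 8 of replicate 2 score above that value. The score was used to rank, split and describe peaks within a list and to set paired peaks side by side, and in 1 test the replicate 1 scores were scaled and held against the lowest score of replicate 2. Read depth is unknown, and no interval given here covers it. Intervals on shares of peaks cover counting error only, and overlap, score and density depend on how many reads the authors had.

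Peak positions were read 1-based as in the files. No peak overlapped another of its own list. A peak counted as shared when at least 1 bp of it overlapped a peak of the other list. The share of shared peaks and the base-pair Jaccard index (bases in both lists over bases in either) were compared with 1000 rotations, in which the other list was shifted around each chromosome by 1 random offset. This keeps the number, width and spacing of peaks, is one-sided, and cannot give a p below 0.001. Shared peaks were paired one to one by largest overlap, and scores of pairs were compared by Spearman's rho and by Pearson's r of log10 scores, with 100000 permutations. Shares have exact Clopper-Pearson 95% intervals. Densities were divided by the span from the lowest start to the highest end of the peaks on each chromosome over both lists, which together come to 99.9 Mb. Ratios of densities have 95% intervals from 10000 bootstrap draws of 500 kb blocks. The share of peaks in the middle 33.3% of each span (the central share) was tested with an exact two-sided sign-flip permutation over the 6 chromosomes. The median distance between neighbouring peak midpoints was compared with 1000 uniform placements, two-sided, with a smallest possible p of 0.002. Nothing in the labels says that the replicates came from separate cultures, and these p-values and intervals are statements about positions in these 2 lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

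The code of the statistics was run on simulated lists before use. The shared share, the X ratio and the central share were built into these lists. Their recovery checks the arithmetic and does not show that p-values or intervals are calibrated. In 3455 simulated peaks of which 59.0% had been copied into a second list, 59.0% were recovered as shared, and all 2038 copies were paired. In 2731 simulated peaks, a density ratio of 0.5 between X and the autosomes came back as 0.50 and a central share of 45% as 45.0%. Randomly placed simulated peaks had a median neighbour distance 0.98 times that of uniform placement. A simulated list placed independently of the other shared 13.6% of its peaks, against a mean of 13.8% under rotation.

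Tests, comparisons and the rule for named regions were fixed before the data were examined. The rule takes the 10 shared regions with the highest mean of the 2 score percentiles and, from each list, the 5 highest-scoring peaks without a partner. The widest shared regions, the longest stretches without a peak, the most discordant pairs, the window counts, the ratios between single chromosomes, the ratios of median scores, the split of X by score quartile, the X ratio and the score correlation without saturated scores, the correlation of pairs below both medians, the central share of the highest score quartile, the placements inside 500 kb windows (with and without joined peaks) and the counts of replicate 1 peaks after scaling of scores were added after the values were seen. That scaling divided replicate 1 scores by the median score ratio of unsaturated pairs, from the pairs above the median geometric mean score and from all of them, with 95% intervals from 2000 bootstrap draws of pairs. Alternatives were other overlap rules and placements, higher score limits, lists of equal length, joined peaks, bases in place of peaks, other block lengths, and each replicate alone. Assignment of peaks to genes and the tests on 12 gene lists had been planned for an annotation of the same genome build. The gene table at hand is of assembly WBcel235, builds were not mixed, and those comparisons were not made, so regions are given by position alone.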

Results

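EPC-1 binding was mapped by ChIP-seq in whole L3 larvae of C. elegans strain N2. EPC-1 is the worm homologue of Enhancer of Polycomb, a subunit of histone acetyltransferase complexes of the TIP60 (NuA4) type. The data comprised 2 replicate immunoprecipitations, each with the authors' own list of peaks, so the comparisons were between the replicates and between parts of the genome. Replicate 1 held 3455 peaks and replicate 2 held 2833, a mean of 3144 ± 440 (SD, n = 2) and a difference of 622. The peaks of replicate 1 covered 6.38 Mb, or 6.38% of the 99.9 Mb between the outermost peaks of the chromosomes, and those of replicate 2 covered 5.86 Mb, or 5.87%. Median peak width was 1559 bp in replicate 1 (quartiles 1346 and 1958.5) and 1697 bp in replicate 2 (1485 and 2199). Median scores were 242 and 244, and the score reached its tied value of 3100 or more in 224 peaks (6.48%) of replicate 1 and 206 peaks (7.27%) of replicate 2. Read depth was unknown.

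The first comparison asked how far the replicates marked the same sites. Nearly every replicate 2 peak lay on a replicate 1 peak, and most replicate 1 peaks lay on a replicate 2 peak. Of the 2833 peaks of replicate 2, 2694 (95.1%, exact 95% interval 94.2 to 95.9) overlapped a peak of replicate 1. Of the 3455 peaks of replicate 1, 2729 (79.0%, 77.6 to 80.3) overlapped a peak of replicate 2. Rotated lists gave 14.5% ± 0.932 (SD over 1000 rotations) and 12.04% ± 0.807, so the observed shares were 6.58 and 6.56 times those of rotation. No rotation came near either share, with maxima of 32.8% and 28.0% (permutation of positions by rotation, one-sided p = 0.001 for both, the smallest that 1000 rotations can give). The lists had 5.12 Mb in common, 80.2% of the bases of replicate 1 and 87.3% of those of replicate 2. Their Jaccard index was 0.719, against a mean of 0.036 under rotation (permutation by rotation, p = 0.001, again the smallest possible). With both lists held to 2833 peaks by score, 88.9% of replicate 1 peaks and 88.1% of replicate 2 peaks were shared.

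Peaks without a partner scored low. In the highest score quartile, 863 of 864 replicate 1 peaks (99.9%, interval 99.4 to 99.997) and all 708 replicate 2 peaks (100%, interval from 99.5% up) had a partner. In the lowest quartile the share was 39.6% (36.3 to 42.9) in replicate 1 and 83.6% (80.7 to 86.3) in replicate 2. The 726 unpartnered peaks of replicate 1 had a median score of 80.1 against 357 in its shared peaks, and were narrower, at a median of 1307.5 bp against 1636 bp. The 139 unpartnered peaks of replicate 2 had a median score of 72.2 against 266.

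**Figure D1:**
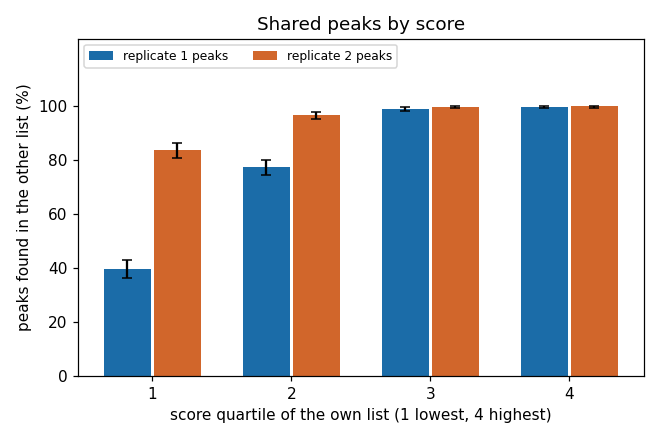
Percentage of peaks that overlap a peak of the other replicate by at least 1 bp, in each score quartile of the peak's own list (bars, with exact 95% intervals that cover counting error only). The lowest quartile stands at 39.6% in replicate 1 and 83.6% in replicate 2, and the highest quartile at 99.9% and 100%.

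Sites also kept their rank. Over 2681 one-to-one pairs the scores of the replicates had a Spearman rho of 0.91 and a Pearson r of 0.93 on the log10 scale (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give). These are correlations across peaks, which are not independent replicates. Among the 923 pairs with both scores below the median of their list, a setting chosen after the data were seen, rho was 0.36. That choice narrows the range of both scores, which can lower a correlation by itself. Without saturated scores, also a setting chosen after the data were seen, rho was 0.88 (2449 pairs). Of the 222 paired replicate 1 peaks at or above 3100, 195 were also at or above 3100 in replicate 2. In the 2449 pairs below that value in both lists, the replicate 1 score was the higher in 1852 (75.6%), with a median ratio of 1.30 (quartiles 1.01 and 1.75). Midpoints of paired peaks lay a median of 48 bp apart. Replicate 2 peaks were the wider in 1920 pairs (71.6%), and over all 2681 pairs the median difference in width, replicate 2 less replicate 1, was 82 bp (quartiles -17 and 181). The narrowest peak of the whole list was 916 bp in replicate 1 and 1179 bp in replicate 2. Whether the difference in width came from the calling of each list was not tested.

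**Figure D2:**
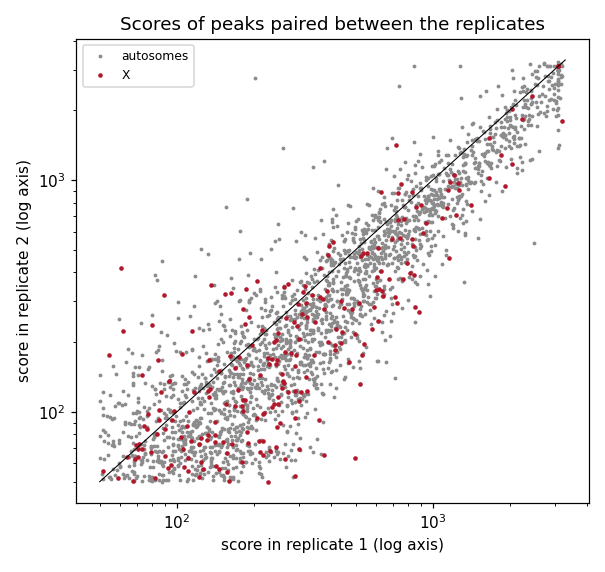
Score in replicate 2 against score in replicate 1 for 2681 paired peaks, on log axes, with X in red, autosomes in grey and the line of equal scores. Most points lie below the line, since the replicate 1 score was the higher in 75.6% of unsaturated pairs, and points gather at the upper right where the score saturates at 3100.

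The 10 shared regions that the fixed rule named lay on chromosomes I to V (WS190 coordinates). X had 4 pairs at or above 3100 in both lists, level with the last of the 10. The first by mean percentile was chromosome I from 5104088 to 5107020, with a score of 3187 in replicate 1 and 3165 in replicate 2, the only pair above 3100 in both lists. Chromosome III held the next, from 12366793 to 12371010 (scores 3100 and 3223) and from 4192713 to 4197599 (3100 and 3123). Others lay on chromosome I from 10788039 to 10789847 (3100 and 3117), on IV from 3049328 to 3051647 (3100 and 3112) and from 4747130 to 4750838 (3147 and 3100), on II from 14398597 to 14400976 (3214 and 3100), and on V from 723656 to 728757 (3128 and 3100). The last of the 10, on chromosome I from 314290 to 317009 and from 533764 to 538055, stood at 3100 in both lists, where ties are broken only by position. Whether a score above 3100 marks a stronger peak than the tied value is not known, since the scale of the score is not stated. The score therefore gave little order among the 195 pairs at or above 3100 in both lists. The order of the named regions is not read as a rank of strength.

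Some shared regions were several times wider than the median. The widest lay on chromosome II from 10541077 to 10560529, where a peak of 12862 bp in replicate 1 and of 19453 bp in replicate 2 carried scores of only 242 and 211. On X, the region from 16928765 to 16941708 was 12344 bp wide in replicate 1 and 12944 bp in replicate 2 and reached 3100 in both. Chromosome V held wide regions from 6219409 to 6229893 (scores 2807 and 1994) and from 7915443 to 7925586 (3100 and 1913), and chromosome I from 7078977 to 7088439 (2810 and 2090).

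Few high-scoring sites were private to a replicate. The highest score without a partner was 910, on chromosome V from 2485725 to 2488931 in replicate 1, where the nearest replicate 2 peak was 111 kb away. The next in replicate 1 were on X from 13526319 to 13528365 (331), on V from 2527885 to 2533679 (289), on IV from 7022471 to 7023826 (276) and on V from 6997008 to 6999231 (262). In replicate 2 they were on III from 2110816 to 2114493 (318), on I from 3389582 to 3393954 (223), on X from 1883101 to 1888331 (206), on IV from 15765049 to 15766969 (198) and on I from 12545911 to 12548846 (194).

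The second comparison was between chromosomes. Peaks were densest on chromosomes I and III, sparser on II and IV, sparser again on V and sparsest on X. In replicate 1 there were 50.01 peaks per Mb on I, 50.73 on III, 36.01 on II, 34.3 on IV, 24.5 on V and 19.7 on X. In replicate 2 the densities were 42.5, 42.1, 30.2, 27.9, 19.9 and 14.5 in the same order. Chromosomes I and III together had 1.43 times the density of II and IV in replicate 1 (bootstrap 95% interval 1.29 to 1.60) and 1.46 times in replicate 2 (1.31 to 1.64). These groups were formed after the densities were seen. A ratio above 1 therefore follows from the grouping, and the intervals describe its size only. The X to autosome ratio was 0.52 (0.46 to 0.59) in replicate 1 and 0.46 (0.40 to 0.53) in replicate 2, a mean of 0.49 ± 0.042 (SD, n = 2). X also lay below V, with ratios of 0.81 (0.68 to 0.96) and 0.73 (0.61 to 0.89). X was the lowest of the 6 chromosomes in both lists, and an exact permutation of 1 chromosome against 5 cannot give a p below 0.167.

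Peaks on X scored lower and were fewer. The median score on X was 170 against 255 on the autosomes in replicate 1, a ratio of 0.67 (bootstrap interval 0.56 to 0.78), and 163 against 257 in replicate 2, a ratio of 0.63 (0.52 to 0.73). Of the 348 X peaks of replicate 1, 5 (1.44%, exact interval 0.468 to 3.32) scored 3100 or more, against 7.05% (6.17 to 8.01) of autosomal peaks. In replicate 2 it was 4 of 256 (1.56%, 0.427 to 3.95) against 7.84% (6.83 to 8.94). By score quartile of the list, the X to autosome ratio of density was 0.68 (0.56 to 0.81) in the lowest and 0.26 (0.18 to 0.34) in the highest quartile of replicate 1, and 0.68 (0.55 to 0.81) and 0.19 (0.12 to 0.27) in replicate 2. X peaks lacked a partner more often than autosomal peaks, at 32.5% against 19.7% in replicate 1 and 7.81% against 4.62% in replicate 2, a difference that was not tested. Low-scoring peaks lacked a partner more often on the whole, and these shares were not adjusted for the lower scores on X.

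**Figure D3:**
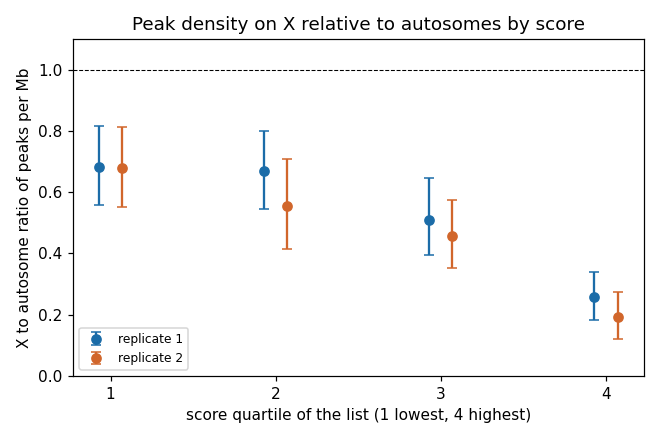
Ratio of peaks per Mb on X to peaks per Mb on the autosomes for each score quartile of each list (points, with 95% intervals from bootstrap draws of 500 kb blocks). The ratio lies below the dashed line of equal density in every quartile, from 0.68 in the lowest of both lists to 0.26 and 0.19 in the highest.

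The third comparison was along the chromosomes. On every autosome more than 33.3% of the peaks lay in the middle 33.3% of the chromosome, whereas on X fewer did, in both lists. In replicate 1 the central share ran from 38.0% on III to 42.3% on V and was 31.03% on X (108 of 348 peaks). In replicate 2 it ran from 35.9% on IV to 41.8% on V and was 27.3% on X (70 of 256). The lower share on X was not tested by itself. Over the 6 chromosomes 38.7% of replicate 1 peaks and 37.2% of replicate 2 peaks were central, and the difference from an even spread did not pass the threshold (exact sign-flip permutation, two-sided p = 0.062 and p = 0.19). Over the autosomes alone the shares were 39.6% and 38.2%, each with an exact p = 0.062, the smallest that 5 chromosomes allow. In the highest score quartile, a setting chosen after the data were seen, the shares over 6 chromosomes were 40.3% in both lists (exact sign-flip p = 0.031 and p = 0.062). The value for replicate 1 is the smallest that 6 chromosomes allow, and it needs all 6 on the same side. In that quartile of replicate 1, X with its 45 peaks therefore also lay above 33.3%, unlike in the full list.

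Peaks also lay nearer to each other than uniform placement would put them. The median distance between neighbouring midpoints was 15.5 kb in replicate 1, against 18.6 kb for uniform placement (central 95% of placements 18.0 to 19.3), and 19.035 kb in replicate 2, against 22.4 kb (21.5 to 23.2). Both differences exceeded every placement (permutation of positions by uniform placement, two-sided p = 0.002, the smallest that 1000 placements can give). In replicate 1, 20.1% of neighbours were within 5 kb, and in replicate 2 15.8%. Among full 500 kb windows, the densest held a mean of 31 peaks over the lists, on chromosome I from 2515893 to 3015892 (32 and 30 peaks) and on III from 9514049 to 10014048 (34 and 28). The emptiest were on V from 3007396 to 3507395 and from 17007396 to 17507395, with 1 peak in each list, followed on II by the window from 1518067 to 2018066, with 1 and 2.

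**Figure D4:**
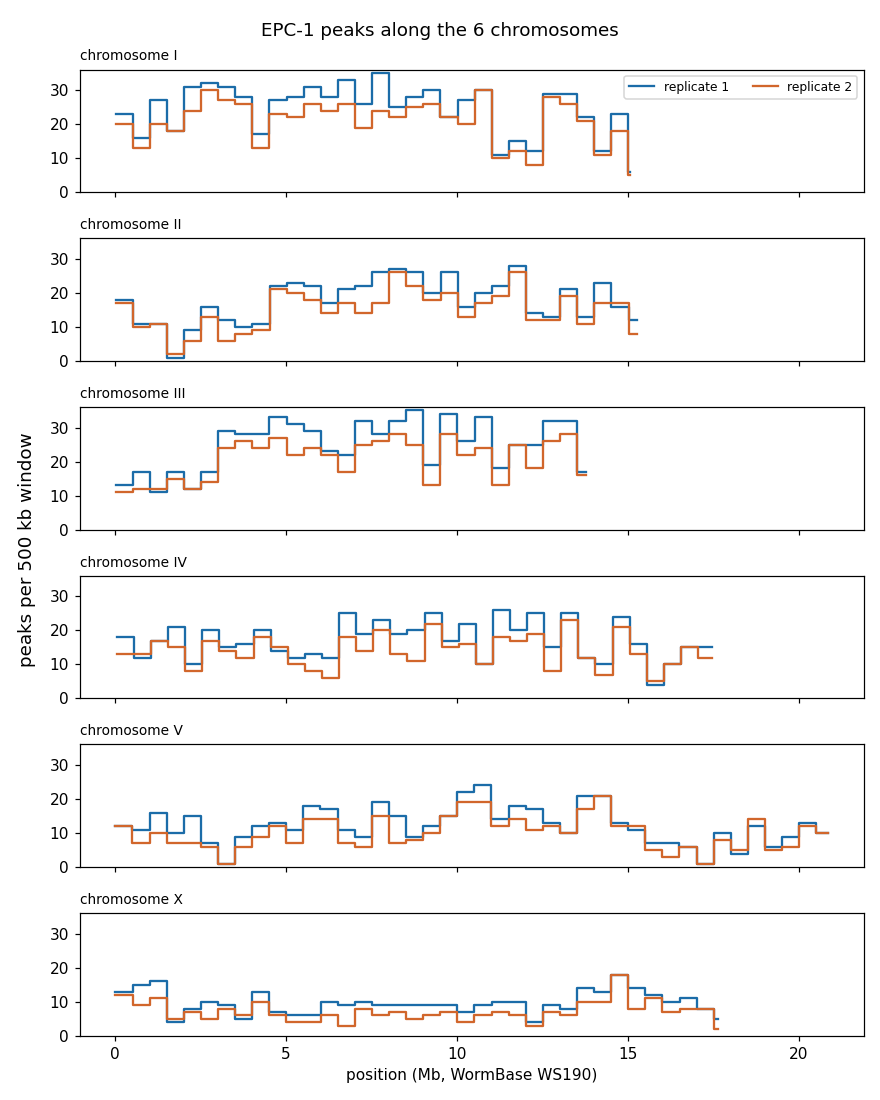
Number of peaks in consecutive 500 kb windows along the 6 chromosomes (x axis in Mb, WS190), replicate 1 in blue and replicate 2 in orange; the last window of each chromosome is shorter. The lists follow each other closely, and full windows held from 1 to 35 peaks in replicate 1 and from 1 to 30 in replicate 2.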

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

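Of 58 recomputed values with a test or a bootstrap interval, 57 kept their direction and their side of the threshold, or of a ratio of 1, which does not mean that their size was kept. This count includes the central shares without X, which could not pass, since 5 chromosomes allow no exact sign-flip p below 0.0625. Every central share counted as kept stayed short of the threshold, as in the full lists. The count also includes uniform placement in place of rotation, and other block lengths. These leave the observed overlap or density ratio itself unchanged. A stricter overlap, at least 50% of both peaks, lowered the shared share of the highest score quartile from 99.9% to 96.5% in replicate 1 and from 100% to 97.7% in replicate 2. Both rules were applied to the same peaks, and the stricter rule can only lower a share. The cause was not tested. The central share of replicate 1 passed the threshold only in the highest score quartile, at 40.3% (exact sign-flip p = 0.031), a setting chosen after the data were seen. The shared shares ranged from 67.4% (midpoints within 200 bp) to 88.9% (equal list lengths) in replicate 1 and from 82.1% to 95.7% in replicate 2, each past every rotation. The X to autosome ratio moved by over 1.5 times only with the highest score quartile alone. Replicates 1 and 2 alone gave X ratios of 0.52 and 0.46, central shares of 38.7% and 37.2%, and neighbour distances of 0.83 and 0.85 times uniform placement. No paired analysis was possible because the inputs, the only other group, have no values here. Assignment to genes, its window sizes and the gene lists were not run, because the annotation is of another build. Unknown depth limits what the absence of a low-scoring peak shows.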

Other observations

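Chromosome V combined few peaks with a share of saturated peaks near that of the autosomes as a whole. Its density was 0.58 times that of the other autosomes in replicate 1 (bootstrap 95% interval 0.50 to 0.67) and 0.56 times in replicate 2 (0.48 to 0.66). V was singled out after it was seen to be the sparsest autosome, so a ratio below 1 follows from that choice. The share of its peaks at or above the tied score of 3100 was 7.44% (exact interval 5.32 to 10.1) and 8.21% (5.75 to 11.3), close to the 7.05% and 7.84% of all autosomes, whereas X had 1.44% and 1.56%. The median score on V was 0.82 times that of the other autosomes in replicate 1 (bootstrap interval 0.71 to 0.98) and 0.98 times in replicate 2 (0.79 to 1.17). Of the 8 longest stretches without a peak in either list, 5 were on V, 2 on X and 1 on II. The longest ran on V from 2827538 to 3387968 (560 kb), followed on V by 17116823 to 17659100 (542 kb) and 18140594 to 18533113 (393 kb), and on X by 3246845 to 3605059 (358 kb).

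A few pairs differed far more than the rest. Of 2681 pairs, 422 scored over 2 times higher in replicate 1 and 71 in replicate 2, while 7 scored over 5 times higher in replicate 1 and 4 over 5 times higher in replicate 2. The highest ratio toward replicate 1, 7.84, was on X from 10765421 to 10769445 (scores 497 and 63.3), and the highest toward replicate 2, 13.6, was on IV from 2312870 to 2317791 (203 and 2758). The region on IV held 2 replicate 1 peaks, of which the other scored 3217, so its ratio arose from the one-to-one pairing by largest overlap.

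All tests that follow were chosen after the data were seen.

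The first pattern is the shortage of X peaks. No test made here decides on its cause, since sites under the authors' threshold are not in the lists and the scores of X peaks belong to the same observation. Sites under the threshold, a lower density of genes on X, a difference in recovery of X chromatin that the inputs would show, and a biological difference in EPC-1 occupancy of X were not tested and stay open.

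The second pattern is the 622 additional peaks of replicate 1. Broad replicate 2 peaks that cover several replicate 1 peaks gave a net 35 peaks, or 5.63% of the difference, which argues against this as the main cause. A single scale between the scores, as measured in paired peaks and with the same lower limit in both lists, also falls short as the whole cause. Division of the replicate 1 scores by the median ratio of 1.24 in the upper unsaturated pairs left 3233 peaks (bootstrap interval 3213 to 3256) at or above the lowest score of replicate 2, and division by the ratio of 1.30 in all unsaturated pairs left 3190 (3165 to 3209), against the 2833 of replicate 2. The replicate 1 peaks lost by these divisions came to 35.7% and 42.6% of the difference of 622, so a single scale may account for a part of it. The 726 unpartnered replicate 1 peaks did not enter either ratio, and the intervals do not cover this selection. The ratio from all pairs may therefore be too low. The upper pairs are less exposed, since 99.1% and 99.9% of replicate 1 peaks in the third and highest score quartiles had a partner. Loss of power that is greater near the threshold, whether from fewer reads, lower enrichment or a different input, was not tested and stays open.

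The third pattern is the short distance between neighbouring peaks. If it came only from regional density, placements that keep the number of peaks in each 500 kb window would give the same distances. The observed medians were 0.86 and 0.88 times those of such placements (permutation of positions inside windows, two-sided p = 0.002 in both lists, the smallest possible), below their central 95% of 17.3 to 18.5 kb and 20.8 to 22.4 kb. Clustering at a scale below 500 kb therefore remained. With peaks within 500 bp joined, the medians were still 0.90 times those of placements inside windows in both lists (permutation inside windows, two-sided p = 0.002, the smallest possible), which argues against splitting of bound regions at that distance as the whole cause. Splitting over longer distances, and clustering of the underlying sites, as near closely spaced genes, were not tested.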
